A study of Mus musculus with 12 samples.

How the data were processed

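The values are single-colour Illumina mouse bead-array signals for 45281 probes on 12 arrays. Per the file headers each array has a column of signal intensity and a column of detection p-value, and 0 value columns were left unused. The authors also deposited a normalized table of intensity on a linear scale, with array medians from 60.03 to 60.67 and with the rank order of the unnormalized signals kept on each array. Its method is not stated, and it was used only as an alternative. Per the labels, RNA was purified with a Qiagen RNeasy Mini kit and labelled with biotin by the Ambion MessageAmp procedure.

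The design, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined. Unnormalized signals were background corrected with limma's neqc from the detection p-values, with an offset of 16, then quantile normalized and put on a log2 scale. Probes with detection p under 0.05 on at least 4 of the 12 arrays were tested, which kept 23516. Of all probes 34885 had 1 gene symbol in the reference table, 18 had several and 10378 had none. Tested probes covered 11698 genes. Probes without a symbol were tested and counted, and none were named. A gene's brightest probe, by mean normalized log2 value and found anew in each fit, stood for it in lists. Opioid genes keep the probe that was brightest over all 12 arrays. Other single genes are given by the probe with the small p-value, and where the gene has a brighter probe its value is printed too.

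A single limma linear model with a mean per group was fitted over all 12 arrays, with 9 residual degrees of freedom before moderation (7 without FC 1 and FC 3). The 3 contrasts were tested by moderated t with p-values adjusted by Benjamini-Hochberg over all tested probes, and a probe was called at adjusted p under 0.05. Exact permutation p-values for single genes compare the difference of means over all 70 arrangements of 4 against 4, with a smallest possible value of 0.0286. With 2 against 4 there are 15 arrangements, with a smallest of 0.0667. They are not adjusted for the number of probes. For genes picked by small p-values, or after the values were seen, they are no separate support. Changes where a probe was detected on no array of a group and on every array of the other are given as at least so many fold.

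Lists of genes were written from general knowledge: 29 lists with 610 different genes, of which 455 had a tested probe. They cover activity and stress responses, transmitter and peptide systems, cell types, neighbouring tissues and regions, oxidative phosphorylation and ribosomal proteins. Each list of at least 5 tested genes was compared with all other genes by limma's camera with a preset correlation of 0.01, and adjusted over all 87 list tests. List scores are means over genes of the log2 deviation from the gene's mean, and were compared with 1000 random lists of genes of like brightness.

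Named genes follow a rule. Oprl1 and every tested gene of the opioid list are named. Up to 10 genes per direction with adjusted p under 0.05 follow, and where fewer than 5 pass, the genes of smallest unadjusted p up to 5 per direction as values that did not pass. Up to 4 genes of each called list are also named. Predicted and unnamed transcripts were passed over. Fos, Arc, Fkbp5, Tac2 and the second Tsc22d3 probe were chosen after the values were seen.

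Other settings chosen beforehand were no background correction, median scaling, cyclic loess, no detection filter, a stricter filter (detection p under 0.01 on all 12 arrays), the authors' normalized values, an intensity trend with a robust prior, array weights, a fit of only the 8 arrays compared, the replicate number as a block, each array left out in turn, 1 probe per gene, a 1.5-fold threshold, a threshold of 0.1 for the adjusted p, estimated correlation and fry for lists, and split HC arrays for the correlation. A block for the slide could not be fitted because the deposited values name no slide. Fits without FC 1 and FC 3, and also without IMO_FC 1, were added after the values were seen.

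The procedure was tested on simulated data with independent probes and, for each probe, 1 spread shared by all groups. With all 12 arrays it called 0% of 100 probes changed 2-fold in each contrast, and 20%, 14% and 13% of those changed 4-fold in FC against HC, IMO_FC against HC and IMO_FC against FC. On the 10 other arrays it called 2%, 13% and 1% of 2-fold and 27%, 62% and 42% of 4-fold changes. False calls were 3 of 23, 0 of 14 and 1 of 14 with all arrays, and 2 of 31, 1 of 76 and 1 of 44 without those arrays. The glucocorticoid list, shifted by log2 0.5, was called in all 6 simulations, with 1 unshifted list called beside it in IMO_FC against FC with all 12 arrays. The number of arrays and the spread between them thus limit what could be found. In the real data FC spreads more widely than the other groups and genes vary together, so these rates are only a rough guide. Versions were R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9.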

Results

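The samples came from the amygdala of male C57Bl/6J mice aged 10 weeks, taken bilaterally with 1 mm punches. Per the labels there were 3 groups of 4 arrays: home-cage mice (HC), mice taken 2 h after fear conditioning (FC), and mice exposed to immobilization before fear conditioning and taken 2 h after it (IMO_FC). Replicates carry separate sample labels, and nothing says that each is a separate animal, so the p-values measure only the spread between these samples. The series concerns Oprl1, the receptor for the peptide nociceptin, in mice and in people with post-traumatic stress disorder. Only mouse arrays were analysed here.

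On 10 of the 12 arrays between 38.97% and 50.7% of probes were detected, and their signals ranked alike, with Spearman rho of 0.77 to 0.933 between pairs. On FC 1 and FC 3 only 11.69% and 15.94% of probes were detected, and rho with the other 10 arrays was 0.219 to 0.312 and 0.314 to 0.409. Of 11633 probes detected at p under 0.01 on all the other 10 arrays, FC 1 retained 27.39% and FC 3 38.92%. Each comparison was therefore made with all 12 arrays, as planned, and again without FC 1 and FC 3, a setting chosen after the values were seen. Without them FC has n = 2.

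Oprl1, the gene named in the series title, encodes the nociceptin receptor, which dampens transmitter release in amygdala circuits. Its transcript level after fear conditioning with or without previous immobilization was examined here. With all 12 arrays the probe of highest mean normalized log2 value was higher in FC than in HC by log2 2.06 ± 0.664 (SE, n = 4 per group, 4.17-fold). It was 0.29 ± 0.664 higher in IMO_FC than in HC. IMO_FC was below FC by −1.77 ± 0.664. None of the 3 differences passed limma's test (adjusted p = 0.297, 1 and 0.356). The exact permutation p was 0.0571, 0.571 and 0.0571. The other Oprl1 probes did not share this pattern, with −1.21 and 0.13 for FC against HC, −0.54 and −0.46 for IMO_FC against HC, and 0.67 and −0.59 for IMO_FC against FC. The high FC mean of the first probe came from FC 1 and FC 3, at 10.46 and 9.466 against 7.736 and 7.095 on FC 2 and FC 4. Their deposited signals of 245.9 and 221.5 lie near the 276 and 210.2 of FC 2 and FC 4, while the median signals of FC 1 and FC 3 were 35.58 and 58 against 66.78 and 72.15. The height on FC 1 and FC 3 thus arose in background correction and quantile normalization, which placed near-equal signals higher on these arrays. Whether it reflects more Oprl1 RNA in those samples was not tested. The other Oprl1 probes were not detected on FC 1 and FC 3. Only through those arrays is the first probe the brightest: without them the second probe is. It gave −0.26 ± 0.378 for FC against HC, −0.55 ± 0.308 for IMO_FC against HC and −0.29 ± 0.378 for IMO_FC against FC. The first probe then gave 0.81, 0.30 and −0.51, and the third 0.86, −0.48 and −1.34, the last with exact p = 0.0667, the smallest that 2 arrays against 4 can give. The direction of the difference between FC and HC thus depends on the probe.

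**Figure D1:**
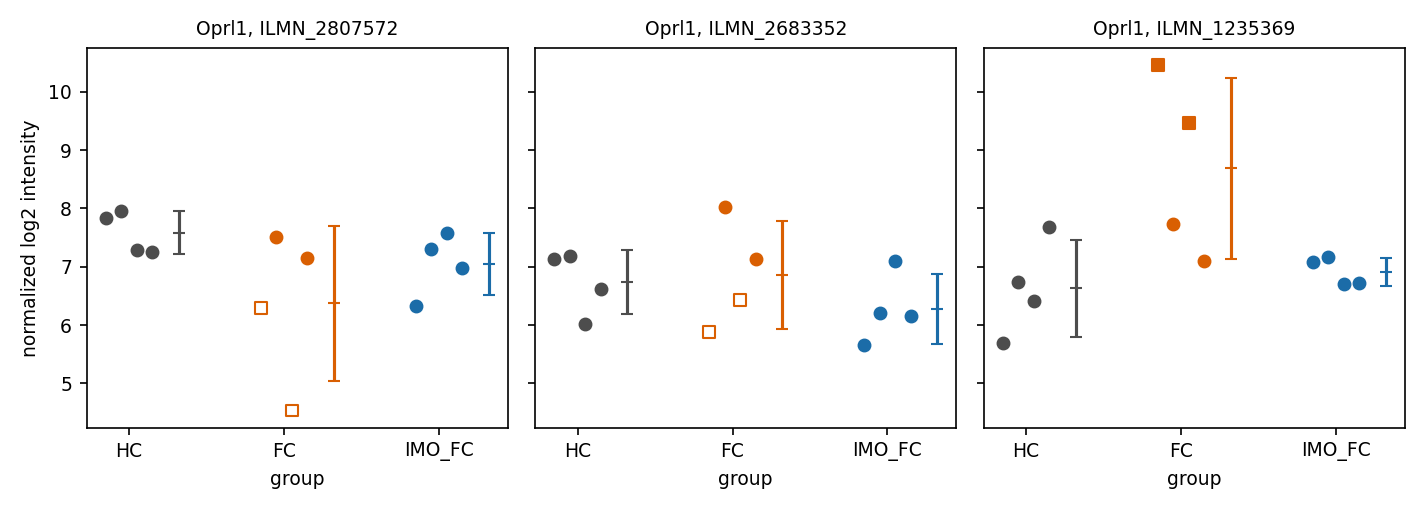
Each panel shows 1 of the 3 Oprl1 probes as normalized log2 intensity on the 12 arrays by group, with a point per array and bars at the mean ± SD. Squares mark FC 1 and FC 3, open symbols arrays where the probe was not detected. On the probe of highest mean normalized value the FC mean of 8.689 ± 1.55 rests on the squares, against 6.627 ± 0.825 in HC and 6.915 ± 0.237 in IMO_FC.

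The rest of the opioid system gave no difference that passed. Between IMO_FC and HC, whose arrays all gave usable signal apart from a weaker IMO_FC 1, Pnoc, the precursor of nociceptin itself, stood at −0.31. Penk and Pdyn, the precursors of enkephalins and dynorphins, stood at 0.51 and 0.0014. Pomc, the precursor of beta-endorphin, stood at 0.10 and Oprk1, the receptor for dynorphin, at −0.17. Ogfr, the receptor of the opioid growth factor, and its relative Ogfrl1 gave −0.24 and −0.059. In FC against HC the planned values were −1.50 for Penk, −1.37 for Pdyn, 1.07 for Pomc, 0.27 for Pnoc, 0.060 for Oprk1, 0.87 for Ogfr and −0.998 for Ogfrl1. On the other 10 arrays they were −0.063, −0.25, 0.057, −0.13, −0.37, 0.21 and 0.048. In IMO_FC against FC the planned values were 2.01 for Penk, 1.37 for Pdyn, −0.96 for Pomc, −0.59 for Pnoc, −0.23 for Oprk1, −1.11 for Ogfr and 0.94 for Ogfrl1. They were 0.57, 0.25, 0.046, −0.20, 0.18, −0.46 and −0.10 without those arrays. Of the 8 list genes tested 0 had adjusted p under 0.05, adjusted over the list alone or over all probes. The list test gave adjusted p = 0.524, 0.983 and 0.496 for the 3 comparisons, with medians of 0.17, −0.03 and −0.41. Without FC 1 and FC 3 the medians were −0.097, −0.12 and −0.029, and the list test gave adjusted p = 0.935, 0.933 and 0.987.

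FC against HC asks what fear conditioning changes in the amygdala 2 h later, when the first wave of activity-induced transcripts has largely decayed and stress-hormone targets are near their height. Activity genes gave no sign of such a wave at 2 h, which cannot tell whether it took place earlier. Fos, the transcription factor gene used as a marker of recent firing, stood at −0.042, and Arc, whose product removes glutamate receptors from synapses, at −0.17. On the other 10 arrays they stood at −0.55 and −0.43. Fkbp5, a co-chaperone that restrains the glucocorticoid receptor and is induced by it, stood at −1.02 with all arrays and at 0.61 ± 0.296 without those FC arrays. Tac2, the neurokinin B precursor that takes part in fear memory in the amygdala, gave 1.33 and 0.96 on its probes, and 0.041 and 0.32 without those arrays. These 4 genes were chosen after the values were seen.

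None of the 23516 probes passed limma's test between FC and HC: 0 had adjusted p under 0.05, the lowest being 0.297. At unadjusted p under 0.05 there were 3933, where chance gives 1176, with 978 higher and 2955 lower in FC. The median over the tested probes was −0.29, against 0.066 over all probes of the array, and values relative to −0.29 are given beside those measured. Among the smallest p-values, none passing, Rflnb, an actin-filament regulator that binds filamin, stood at −2.82 ± 0.485 (−2.52 relative to the median). Enpp6, a choline phosphodiesterase of newly forming oligodendrocytes, stood at −2.63 (−2.33), and Hook1, which links cargo to microtubules, at −2.19 (−1.89). Fancd2os, an antisense neighbour of a DNA-repair gene, gave −1.92 (−1.62). Ovol2, a repressor of mesenchymal genes not detected in FC, was at least 1.12-fold lower, and at least 3.38-fold lower without FC 1 and FC 3. On the higher side stood Focad, a focal adhesion protein, at 2.25 (2.55) and Eipr1, which helps sort dense-core vesicle cargo, at 2.15 (2.44). Thsd7a, an endothelial guidance protein, gave 1.57 (1.86) and Olfr380, an odorant receptor, 2.29 (2.59). Gjb2, a connexin of meningeal and glial gap junctions, gave 1.82 (2.11). It was detected on no HC array and only on FC 2 and FC 4 in FC, where it was at least 2.29-fold higher. Each had exact permutation p = 0.0286, the smallest that 4 against 4 can give. As these genes were picked for small p-values on the same arrays, that value is no separate support. Brighter probes of the same genes went the other way for Eipr1 (−1.73), Focad (−1.27), Gjb2 (−0.69) and Thsd7a (−0.64), and the same way for Hook1 (−1.25). On the other 10 arrays these probes gave 0.061, −0.43, −0.20, −0.29 and −1.39, so that of Eipr1 no longer went the other way. Without FC 1 and FC 3 the median over all probes was −0.00115, 0 of 23260 probes passed (lowest adjusted p = 1), and 805 had unadjusted p under 0.05 where chance gives 1163. Rflnb then stood at −2.36, Enpp6 at −2.24, Hook1 at −1.41, Fancd2os at −1.67, Focad at 1.30, Eipr1 at 1.98, Thsd7a at 1.15 and Olfr380 at 1.37.

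No gene list separated FC from HC, with a lowest adjusted p = 0.21 over the 29 lists, that of blood genes, whose median was 0.65 (4 of 6 higher) against −0.34 over all genes. Oligodendrocyte precursor markers came next at 0.36 (6 of 9 higher, adjusted p = 0.221). Immediate early genes stood at −0.35 (16 of 47 higher), glucocorticoid targets at −0.29 (20 of 45), circadian genes at −0.59 (5 of 16), inflammation genes at 0.16 (6 of 12), heat shock genes at −0.94 (3 of 19), unfolded protein response genes at −0.65 (5 of 20) and cholesterol synthesis genes at −0.82 (3 of 16). Immediate early genes thus lay near the median of all genes. Without FC 1 and FC 3, where that median was −0.011, the low values mostly came near it. Heat shock genes then stood at −0.020, cholesterol genes at −0.095 and immediate early genes at −0.012. In the glucocorticoid list 33 of 45 genes, Fkbp5 and Tsc22d3 among them, were higher in FC with a median of 0.21, at adjusted p = 0.192. Endocannabinoid genes then had a median of 0.34 (7 of 10 higher, adjusted p = 0.312) and inflammation genes 0.30 (8 of 12, adjusted p = 0.668).

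IMO_FC against HC asks what immobilization and fear conditioning together leave in the amygdala. It did not use the FC means, although FC 1 and FC 3 entered the shared estimate of spread. Among the smallest p-values on the higher side was that of Tsc22d3, a glucocorticoid-induced leucine zipper that carries part of the anti-inflammatory action of corticosterone, at 1.70 ± 0.542 with all arrays and 1.82 ± 0.281 (3.52-fold) without FC 1 and FC 3. Msto1, which governs mitochondrial fusion and distribution, stood at 1.60 ± 0.393 and then 1.72 ± 0.301, and Tomm6, a small subunit of the outer mitochondrial membrane translocase, at 1.73 and then 1.84. None of these passed the planned test. All had exact permutation p = 0.0286, which is no separate support for genes picked by p-value on these arrays. With array weights, a method chosen beforehand that gives each array a weight by its spread, Tsc22d3 rose by 1.63 ± 0.226 (3.1-fold) and Msto1 by 1.38 ± 0.193 (2.59-fold), both with adjusted p = 0.0313. In HC these probes lay near background, that of Tsc22d3 detected on 2 of 4 arrays and that of Msto1 on 1, so the folds are uncertain. Over all settings tried the adjusted p of each ran from 0.0313 to 1. A second and much brighter Tsc22d3 probe, detected on all HC arrays, gave 0.47 (1.39-fold, adjusted p = 0.755) with array weights. It gave 0.43 with all arrays unweighted, and 0.41 ± 0.184 without the 2 weak FC arrays, with exact permutation p = 0.0286.

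In the planned test of IMO_FC against HC, limma called 0 of 23516 probes, and the lowest adjusted p was 1. Only 94 probes had unadjusted p under 0.05 (36 higher, 58 lower) where chance gives 1176, as the wide spread within FC enters the shared estimate. With FC 1 and FC 3 left out there were 737 (324 higher, 413 lower), still under the chance count of 1163. The median over all probes was −0.0056. Also among the smallest p-values, Dennd2c, an activator of Rab proteins not detected in HC, was at least 2.35-fold higher through IMO_FC 1 at 7.903 (5.051 to 5.748 on the other IMO_FC arrays, and a log2 difference of 1.03 without it), and Heph, a copper ferroxidase not detected in HC, at least 1.7-fold higher. Ctnnal1, a catenin relative, stood at −1.34, Cwc22, a splicing factor, at −1.18, and Kdm4a, a histone demethylase, at −1.39. Dio3, the deiodinase that inactivates thyroid hormone, stood at −1.16, all with exact permutation p = 0.0286, and Rnf41, a ubiquitin ligase that limits neuregulin receptors, at −1.66 with exact p = 0.0857. Brighter probes gave 0.15 for Tomm6, −0.37 for Heph, −0.20 for Rnf41 and 0.090 for Cwc22. Tac2 had 0.99 on 1 probe (exact permutation p = 0.0286) and 0.35 on the other (exact p = 0.0857). Fkbp5 stood at 0.47 (exact p = 0.0857), Fos at −0.15 and Arc at 0.39.

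**Figure D2:**
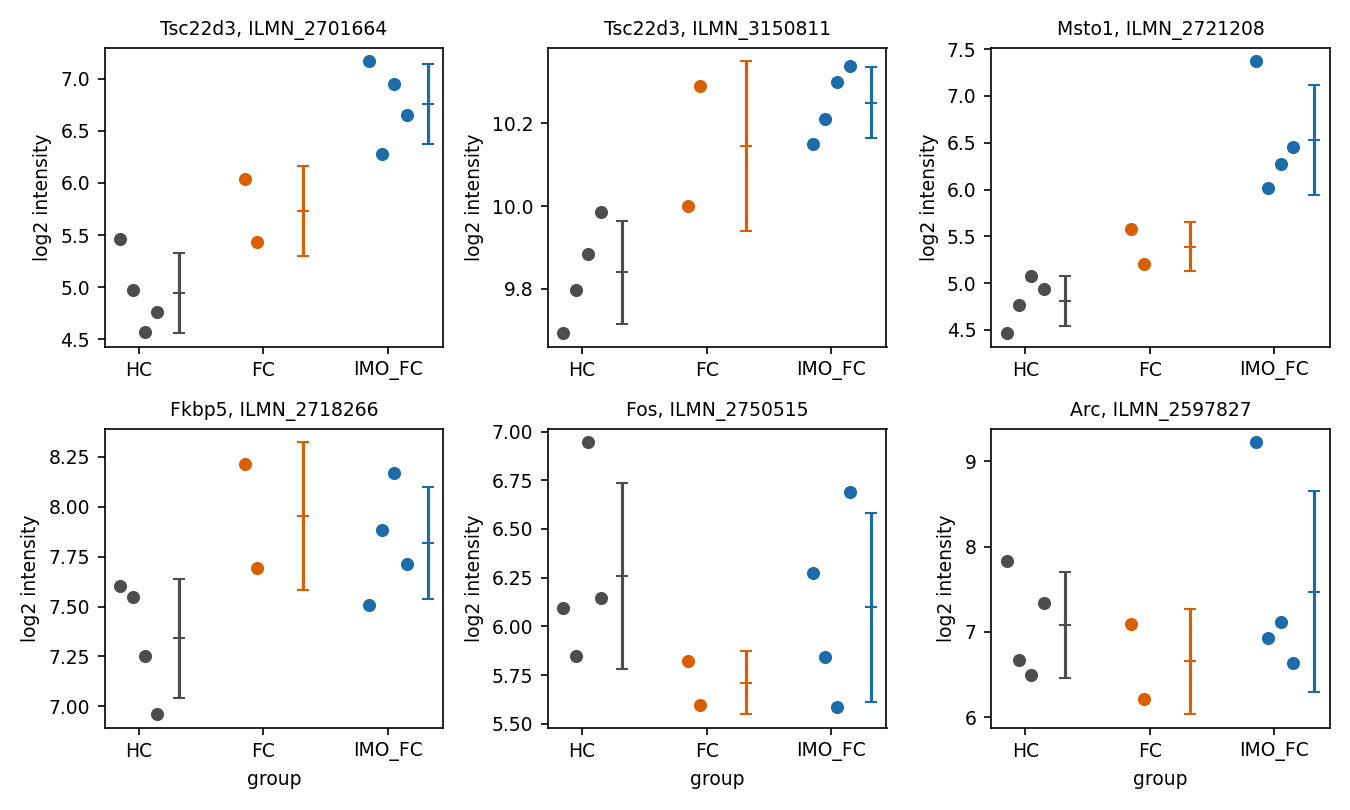
Normalized log2 intensity of both Tsc22d3 probes, Msto1, Fkbp5, Fos and Arc on the 10 arrays left without FC 1 and FC 3, by group, with a point per array and bars at the mean ± SD. The first Tsc22d3 probe and Msto1 lie higher in IMO_FC than HC by 1.82 and 1.72, and Fos differs by −0.16.

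Choroid plexus genes were the only list that separated IMO_FC from HC. Of the 7 tested, 6 were lower in IMO_FC, with a median of −0.51 and adjusted p = 0.0071. With an estimated correlation between its genes the same list had adjusted p = 0.994, and limma's fry gave 0.427. Ttr, the thyroxine carrier that the choroid plexus secretes, stood at −2.95 ± 1.44 (exact p = 0.0857). Aqp1, the water channel of its epithelium, stood at −2.12 ± 0.796 (exact p = 0.143), Col8a1, a basement membrane collagen, at −0.79 and Sostdc1, a secreted BMP inhibitor, at −0.51. None of the 4 passed, and 0 of the 7 genes passed adjusted over the list alone. When FC 1 and FC 3 were left out the list had a median of −0.54 and adjusted p = 0.116. In FC against HC it was then lower too, with a median of −0.57 (6 of 7 lower, adjusted p = 0.307). On single arrays Ttr ran from 7.747 to 11.61 in HC and from 5.665 to 8.212 in IMO_FC, so the spread inside HC is as wide as the difference. HC 1 and HC 2 held the high values, at 11.52 and 11.61 against 8.076 and 7.747 on HC 3 and HC 4. The 8 choroid plexus genes too dim for the test differed by −0.36 (exact permutation p = 0.429).

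Signalling lists were flat between IMO_FC and HC. Stress neuropeptide genes stood at −0.049 (15 of 35 higher), GABA genes at −0.036 (9 of 19), glutamate genes at 0.062 (20 of 34), endocannabinoid genes at −0.067 (4 of 10) and monoamine genes at −0.040 (11 of 22). Immediate early genes stood at 0.0090 (25 of 47 higher), glucocorticoid targets at 0.0024 (23 of 45) and inflammation genes at −0.031 (6 of 12). Heat shock, unfolded protein response, circadian and cholesterol genes stood at 0.034, 0.043, −0.061 and −0.018. With all arrays, and without FC 1 and FC 3, each of these lists had 0 genes with adjusted p under 0.05, adjusted over the list alone. Leaving out IMO_FC 1 as well gave 2 monoamine genes (lowest adjusted p = 0.0387) and 1 heat shock gene (0.0423) over the list alone, and 1 meningeal gene (0.0215). With all arrays none but choroid plexus had a list adjusted p under 0.05.

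IMO_FC against FC isolates what previous immobilization adds to fear conditioning, and like FC against HC it rests on the weak FC arrays. With all arrays limma called 0 probes (lowest adjusted p = 0.356), with 3225 at unadjusted p under 0.05 (2518 higher, 707 lower) around a median of 0.28. Rflnb, low in FC, stood at 2.11 (1.83 relative to that median), Pigu, a subunit of the enzyme that attaches lipid anchors to proteins, at 1.97 (1.69), Arid4b, a chromatin repressor subunit, at 2.21 (1.93), Pdzk1, a scaffold for transporters, at 1.89 (1.62) and Pdxdc1, a decarboxylase domain protein, at 1.88 (1.60). Cdc42se2, an effector of the actin regulator Cdc42, stood at −2.71 (−2.99), Styx, a catalytically dead phosphatase, at −2.30 (−2.58), Olfr380 at −2.25 (−2.53), Ccdc166, a coiled-coil protein, at −1.76 (−2.04) and Gjb2 at −1.72 (−2.00). All, again picked by p-value on the same arrays, had exact permutation p = 0.0286, and none passed. Brighter probes gave 0.75 for Pdxdc1, 0.46 for Pdzk1, 0.65 for Cdc42se2 and 0.42 for Gjb2, the last 2 in the other direction. On the other 10 arrays these probes gave 0.28, 1.47, −0.23 and −0.086, all in the direction of the named probes. Without FC 1 and FC 3 the median was −0.0059 and 0 probes passed (lowest adjusted p = 1), with 813 at unadjusted p under 0.05 where chance gives 1163. Rflnb then stood at 1.64, Pigu at 1.38, Arid4b at 1.18, Cdc42se2 at −1.96 and Gjb2 at −1.21. Of the lists, 0 were called (lowest adjusted p = 0.21). Without those arrays the endocannabinoid list had the lowest value, with 1 of 10 genes higher in IMO_FC, a median of −0.20 and adjusted p = 0.276.

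Markers of cell types and neighbouring regions show how alike the punches were. Between IMO_FC and HC, neuron markers stood at −0.059, astrocyte at −0.11, oligodendrocyte at −0.014, oligodendrocyte precursor at −0.0076, microglia at −0.056, endothelial at −0.055 and mural cell markers at 0.0097. Meningeal genes stood at −0.27, striatal at 0.18, central amygdala at −0.20, basolateral amygdala at −0.071 and thalamic and hypothalamic genes at 0.096. Oxidative phosphorylation and ribosomal protein genes stood at 0.0048 and −0.078. Blood genes were higher for 6 of 6 genes with a median of 0.29 (adjusted p = 0.215), and without FC 1 and FC 3 they stood at 0.43 in IMO_FC (adjusted p = 0.108) and 0.42 in FC (adjusted p = 0.16) against HC. Leaving out IMO_FC 1 as well brought the IMO_FC value to 0.21 (adjusted p = 0.347). In FC against HC with all arrays the median over all genes was −0.34. There 62 of 76 oxidative phosphorylation genes, 43 of 58 ribosomal protein genes and 16 of 18 neuron markers were lower. Their medians were −0.56, −0.79 and −0.75, and the list test gave adjusted p = 0.357, 0.338 and 0.338. These shifts rest on FC 1 and FC 3: on the other 10 arrays the medians were 0.010, −0.049 and 0.055.

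Scores of some of these lists differed widely between arrays of a single group. On the 10 arrays left without FC 1 and FC 3, the striatal score of 16 genes had a within-group SD of 0.487, where 95% of random lists of like brightness stayed under 0.241. It ran from −0.72 to 0.402 in HC and from −0.505 to 0.518 in IMO_FC. Central amygdala genes had an SD of 0.329 (random 0.243), choroid plexus genes 0.53 (0.344), meningeal genes 0.429 (0.284) and oligodendrocyte genes 0.258 (0.198). Stress neuropeptide, GABA and ribosomal protein genes also lay above their random limits, at 0.197, 0.204 and 0.139 against 0.165, 0.193 and 0.116. When IMO_FC 1 was left out as well the GABA value was 0.0829, under its limit of 0.147, while stress neuropeptide genes had 0.203 (0.129) and ribosomal protein genes 0.113 (0.0688). The striatal, choroid plexus, central amygdala, meningeal and oligodendrocyte lists then had 0.486, 0.529, 0.262, 0.324 and 0.276, above limits of 0.166, 0.28, 0.195, 0.25 and 0.139. Astrocyte, inflammation, endothelial and oxidative phosphorylation genes also lay above theirs on these arrays, at 0.161, 0.239, 0.225 and 0.0833 against 0.144, 0.22, 0.217 and 0.0614. Neuron markers, at 0.128, lay under their limit of 0.158.

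**Figure D3:**
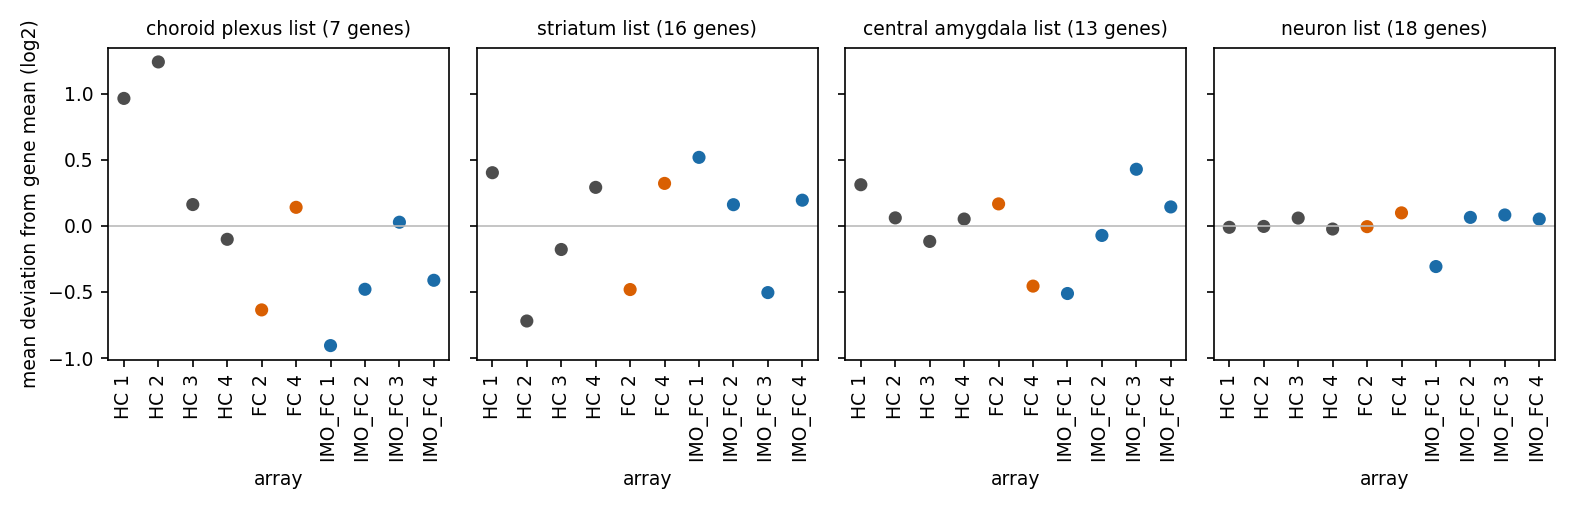
Points show, for each of 10 arrays by group, the mean deviation from the gene mean in log2 over choroid plexus, striatum, central amygdala and neuron genes. HC 1 and HC 2 lie at 0.964 and 1.24 for choroid plexus against 0.161 and −0.102 for HC 3 and HC 4, and the striatum score spreads within every group.

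Changes against HC were compared between the FC and IMO_FC groups over all 23516 tested probes. The correlation of the log2 differences was r = 0.309 (rho 0.323). Both differences subtract the same HC arrays, and simulated unchanged groups of equal spread gave r = 0.499. With the HC arrays split so that each difference had its own 2, the mean r was 0.132 over 6 splits (0.0755 to 0.167), where simulated unchanged groups of independent probes gave −0.0136 to 0.0141. Leaving out FC 1 and FC 3 gave r = 0.397 against a simulated 0.41, and the split values ran from −0.0503 to 0.0764. The simulated groups had equal spread, while FC 1 and FC 3 widen the spread of the real FC group. A wider FC group lowers the unsplit r by itself. With all arrays its place below the simulated value thus tells nothing of a shared response. Real probes also vary together, unlike the simulated ones, so the split value above its simulated range does not settle whether FC and IMO_FC share a response.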

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

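All tests of single patterns here were chosen only after the result was seen; the counts over regrouped arrays were planned before.

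FC 1 and FC 3 stand apart from the other 10 arrays. Fear conditioning itself is an unlikely cause, because FC 2 and FC 4 had the same treatment and their lowest rho with the HC arrays was 0.839. Little labelled material on these arrays could explain the gap, since loss then grows toward dim probes: with the probes detected on all 10 others in 5 equal classes by brightness, the brightest class was retained 5 times as often as the dimmest on FC 1 and 3.96 times as often on FC 3. RNA of another tissue stays open. Probes seen on none of the 10 others were detected at 0.706 times the chance rate, but arrays with so few detected probes could gain few. Arrays of good signal also lay under that rate, such as FC 4 with 81 probes where chance gives 151.06, while others such as HC 1 lay above (218 against 155.92). Degraded RNA would give the same loss of dim probes and stays open.

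The choroid plexus list was called lower in IMO_FC than HC, a call that was lost with an estimated correlation (adjusted p = 0.994), with fry (0.427) and without FC 1 and FC 3 (0.116). Unequal shares of choroid plexus tissue in the punches may be the cause. The genes too dim for the list test varied within groups together with those in it (r = 0.668 over 10 arrays, permutation p = 0.296). Among them Cldn2 stood at 7.23 and 7.364 on HC 1 and HC 2, and at most at 4.816 on the other arrays. Otx2 stood at 6.203 and 6.181 there, and at most at 4.588 elsewhere. Kcne2 and Folr1 were also highest on HC 1 and HC 2, while Calml4, Tmem72, F5 and Steap1 were not. More choroid plexus tissue in those HC punches would give high values there, but the permutation test leaves the matter open. The HC arrays share a treatment, yet HC 1 and HC 2 scored 0.964 and 1.24 on the list. HC 3 and HC 4 scored 0.161 and −0.102, and the IMO_FC arrays −0.906, −0.48, 0.0274 and −0.412. The gap within HC argues against immobilization and fear conditioning as the source of that part of the difference. For the rest they stay open, since the 8 dim genes, each detected on few arrays, differed by −0.355 with exact permutation p = 0.429.

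Striatal genes differ between arrays of a single group. Their within-group SD of 0.487 lies above the random limit of 0.241, which measures the pattern and does not tell its cause, so different shares of neighbouring striatum in the punches stay open. Signal strength of the arrays is a less likely cause, since the striatal SD was still 0.486 without IMO_FC 1, the weakest of these arrays. Neuron markers had an SD of 0.128, and 0.0409 without IMO_FC 1, but they need not respond to weak signal as striatal genes do.

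Regrouping the 8 arrays of a comparison in all 35 ways tells whether chance can be excluded only where the real count is above 0. No probe was called in any comparison, so 35 of 35 groupings reach that count by necessity in each, and this says nothing about chance. The highest other count was 0 for FC against HC, 0 for IMO_FC against HC and 934 for IMO_FC against FC. The last grouping set FC 1, FC 2, FC 3 and IMO_FC 1 against the rest and points to a structure of array quality, since these were the FC and IMO_FC arrays of fewest detected probes. For the counts above 0 chance could not be excluded. Probes at unadjusted p under 0.05 were as many in 5 of 35 groupings for FC against HC (3933 real, 4477 highest other), 25 for IMO_FC against HC (94 and 216) and 9 for IMO_FC against FC (3225 and 6638). Lists called for IMO_FC against HC were as many in 18 of 35 (1 real, 3 highest other).

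Single arrays far from their group were sought by Dixon's test at 0.05 in 110 groups of 4, where chance alone gives about 5%, and 12 (10.9%) were found. IMO_FC 1 had 38.97% of probes detected against 49.62% on the next array of its group. Its median rho of 0.788 lay under 0.907 for the next. Ogfr on FC 1 was 10.57 against 7.914 for the next FC array. Ogfrl1 was 4.505 on FC 1 against 9.554, and 9.134 on HC 4 against 9.602 for the next HC array. Enpp6 was 6.193 on FC 4 against 4.617, Fancd2os 5.879 against 4.5 and Pdxdc1 6.943 against 5.446 on the same array. Oprk1 was 4.627 on IMO_FC 1 against 4.827. On HC 3 Rnf41 was 4.696 against 6.629 and Ctnnal1 5.475 against 6.5. Ccdc166 was 5.623 on IMO_FC 3 against 4.753.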

How the results depend on the processing

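Fits without FC 1 and FC 3, and also without IMO_FC 1, were chosen only after the result was seen, and all other settings here before. Of 1614 recomputed values of named genes 1535 kept their direction and their side of the threshold, 68 reversed and 11 passed it. As no named gene passed in the planned fit, keeping the side means only that it still did not pass. Many of these genes were picked for small p-values on the same arrays, which favours a stable direction, so the share kept does not measure robustness. Reversals lie mostly in FC against HC and IMO_FC against FC.

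Probes called stayed at 0 except with array weights, where IMO_FC against HC gave 2, and without FC 4, where FC against HC gave 58 (16 higher, 42 lower) and IMO_FC against FC 76 (64 higher, 12 lower), 43 of them in both. Leaving out FC 4 leaves FC mostly to its weak arrays. Over single arrays left out the counts ran from 0 to 58 and 0 to 76. Probes at unadjusted p under 0.05 in FC against HC were 1499 without FC 1, 1282 without FC 3, 7162 without FC 2 and 7469 without FC 4, and 1924 to 2173 without an HC array. In IMO_FC against FC they were 1341, 1249, 6525 and 6956 without those FC arrays, and 1625 to 1667 without IMO_FC 2, 3 or 4. In IMO_FC against HC they ran from 55 to 193. Array weights gave 1097, 1556 and 1298 in the 3 comparisons. Cyclic loess gave 1651, 757 and 1227, only the 8 arrays compared 1600, 762 and 1026, median scaling 5638, 267 and 3782, and no filter 4611, 319 and 3700, and the intensity trend with a robust prior gave 142 in IMO_FC against HC. Without FC 1, FC 3 and IMO_FC 1 they were 1495, 853 and 1308, with 0 called. Adjusted over the list alone, that fit also called 2 inflammation genes in FC against HC (lowest adjusted p = 0.0173) and 1 thalamic and hypothalamic gene in IMO_FC against FC (0.0381). With the replicate number as a replicate block 0 probes were called in each comparison, 4304, 88 and 3540 had unadjusted p under 0.05, and choroid plexus had adjusted p = 0.0115.

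Lists called in IMO_FC against HC, 1 as planned, were 0 with cyclic loess, the stricter filter (choroid plexus then too few to test), array weights, only the 8 arrays compared (adjusted p = 0.17), an estimated correlation, fry, and without FC 1 and FC 3 with or without IMO_FC 1. With single arrays left out the count ran from 0 to 2. It was 0 without IMO_FC 2 (adjusted p = 0.0891) or FC 3 (0.0663), and 2 without IMO_FC 1 (meninges added) or IMO_FC 3 (striatum added). In FC against HC 8 lists were called with no filter and 1, oxidative phosphorylation, with the stricter filter. In IMO_FC against FC 9 were called with no filter, 1 (oxidative phosphorylation) with the stricter filter and 3 (choroid plexus, meninges, oxidative phosphorylation) with median scaling. The median over all probes in FC against HC, −0.294 as planned, was −0.749 with median scaling, 0.0443 with cyclic loess, 0.337 with the stricter filter and −0.193 in the authors' values.

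Reversed signs in FC against HC were: no background correction, Fos 0.095 and Arc 0.062; median scaling, Pnoc −1.04, Oprk1 −0.26, Pomc −0.017, Ogfr −0.42 and Tac2 −0.030 and −0.024. Cyclic loess reversed Oprk1 to −0.28, Ogfrl1 to 0.95, Arc to 0.83 and Fkbp5 to 0.42, and the authors' values Fos to 0.092. Array weights gave Pnoc −0.20, Oprk1 −0.33 and Fkbp5 0.45. In the fit without FC 1 and FC 3 Pnoc stood at −0.13, Oprk1 at −0.37, Ogfrl1 at 0.048 and Fkbp5 at 0.61, and without IMO_FC 1 as well at −0.13, −0.39, 0.048 and 0.61.

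In IMO_FC against HC median scaling gave Pdyn −0.085 and Pomc −0.0054, the authors' values Pdyn −0.0012, array weights Arc −0.047, and the fit without FC 1, FC 3 and IMO_FC 1 Pnoc 0.014 and Arc −0.19. In IMO_FC against FC median scaling gave Pnoc 0.58, Oprk1 0.10, Pomc 0.012 and Ogfr 0.061, cyclic loess Oprk1 0.12 and Ogfrl1 −0.95, and array weights Pnoc 0.11 and Oprk1 0.19. Without FC 1 and FC 3 Oprk1 was 0.18, Pomc 0.046 and Ogfrl1 −0.10, and without IMO_FC 1 as well Pnoc 0.14, Oprk1 0.26 and Ogfrl1 −0.093.

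Over single arrays left out, FC against HC ran from −0.30 to 0.66 for Pnoc, −0.22 to 0.26 for Oprk1, −1.67 to 0.34 for Ogfrl1, −0.90 to 0.47 for Fos and −1.17 to 0.62 for Arc. IMO_FC against HC ran from −0.026 (without HC 1) to 0.63 for Oprl1, −0.51 to 0.012 for Pnoc, −0.14 to 0.097 for Pdyn, −0.024 to 0.19 for Pomc, −0.34 to 0.067 for Fos and −0.19 to 0.67 for Arc. IMO_FC against FC ran from −0.43 to 0.039 for Oprk1 and −0.40 to 1.61 for Ogfrl1.

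The planned correlation of r = 0.309 was 0.485 with the stricter filter, 0.132 with split HC arrays, 0.397 without FC 1 and FC 3, and 0.118 (without IMO_FC 1) to 0.349 with single arrays left out.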

Other observations

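Both hypotheses given here were tested by means chosen only after the result was seen.

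Single mitochondrial genes lie among the smallest p-values of IMO_FC against HC. Msto1, which keeps mitochondria spread through the cell, and Tomm6, which helps import their proteins, stood at 1.60 and 1.73 log2 above HC beside Tsc22d3 at 1.70, and none of them passed the planned test. Brighter probes of Tomm6 and Tsc22d3 gave only 0.15 and 0.43. The 76 oxidative phosphorylation genes had a median of 0.0048, with 42 of 76 higher. Genes of mitochondrial fusion and protein import were not tested as a list.

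Enpp6, an enzyme of newly forming oligodendrocytes, was read beside the markers of its lineage on single arrays. It stood at 4.679 on FC 2 and 6.387 on FC 4, where the oligodendrocyte list scored −0.459 and 0.369. In IMO_FC it was lowest on IMO_FC 3, at 4.652, where the list was also lowest of its group at −0.126. Elsewhere they parted: Enpp6 was highest of its group on HC 2 (8.284) and IMO_FC 1 (7.569), where the list scored −0.111 and −0.0822. Whether Enpp6 differs apart from its lineage is not settled by these arrays.

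Tsc22d3 may be higher in IMO_FC through glucocorticoid action on the amygdala of the immobilized and conditioned mice. A hormone effect would raise other targets too, but the glucocorticoid list had adjusted p = 0.891 in IMO_FC against HC without FC 1 and FC 3, with 23 of 45 genes higher, so the hypothesis stays open. Fkbp5 then stood at 0.48 in IMO_FC and 0.61 in FC against HC. In FC against HC, with n = 2 in FC, the 2 Tsc22d3 probes gave 0.79 (exact permutation p = 0.2) and, for the brighter, 0.31 (0.0667). IMO_FC against FC gave 1.03 (exact permutation p = 0.0667) and 0.10 (0.4). Whether the rise is particular to IMO_FC is thus not settled. In FC against HC 33 of 45 list genes were higher (adjusted p = 0.192). Blood corticosterone and more arrays per group would decide it.

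Placement of the punch could make striatal and central amygdala genes move in opposite ways, as a punch set more to the side takes more striatum. Over 10 arrays the list scores had r = −0.482 (permutation p = 0.158) and rho = −0.442 (permutation p = 0.204). Without the 2 arrays farthest out r was −0.354, and within groups −0.517. This was the only relation examined and the lists share 0 genes. The hypothesis stays open, and histology of the punches would decide it.

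The sample labels speak of fear conditioning, while the series text speaks of fear expression and extinction. With 4 arrays per group, and 2 of 4 FC arrays of low signal, an effect of fear conditioning or of previous immobilization on Oprl1 can be neither shown nor excluded by these arrays.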
